A study of Arabidopsis thaliana with 8 samples.

How the data were processed

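Total RNA from Arabidopsis thaliana Col-0 plants was hybridised to 8 single-colour Agilent gene expression arrays. The labels give 3 groups: a methanol mock (3 arrays), (+)-borneol (3 arrays) and (-)-borneol (2 arrays), the borneols at 25 mM, each for 24 h, and describe the arrays of a group as biological replicates. RNA was extracted with a plant RNeasy kit and labelled with Cy3 through Agilent's low-input amplification kit. The arrays lie on 2 slides of 4 arrays, and each slide carries all 3 groups: slide 1 holds mock replicate 1, (+)-borneol replicates 1 and 2 and (-)-borneol replicate 1, and slide 2 holds the other 4 arrays.

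Per the file headers, the scanner tables were made with Agilent Feature Extraction 10.5.1.1, and their processed signal is an intensity for each spot after background subtraction and detrending within the array, with no scaling between arrays. The deposited workbook also holds intensity values without scaling between arrays, although its name calls it normalised: 99.89% of its probe values lay within 0.1% of the processed signal of the scanner tables. Its columns for mock replicates 2 and 3 hold the values of each other's scanner tables, so replicate numbers here are those of the scanner tables. The scanner tables also carry other values per spot, flags for saturation, for outliers and for signal well above background, and no spot was saturated.

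The processed signal was averaged over the spots of a probe, converted to log2, and reduced by the 75th percentile of the array's non-control probes. Spots with an outlier flag were left out of the averages. Of 43603 probes, 5190 name no locus. Of the 38413 that name a locus, 556 were left out because flags left them without a value on at least 1 array. Each locus was represented by its brightest probe, and loci well above background on at least 2 of the 8 arrays were tested, which kept 22748 of 29030. Probe positions are those of the array's own annotation, whose build is named after the year 2004. Of the tested loci, 98.9% were found in a reference table of gene symbols, which was used for names only.

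All comparisons come from 1 linear model per locus over the 8 arrays, with group as the factor and no block, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with data.table (version 1.17.8) for reading. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 22748 loci. Standard errors and 95% intervals are those of the moderated model. Sums over many genes used 24 lists of named Arabidopsis genes (471 genes, 446 of them tested) and 1 list defined by rule, the 369 tested loci annotated as transposable element genes. Each list was tested against the other genes with limma camera at a preset correlation between genes of 0.01, and beside it with an estimated correlation and with limma fry. Adjusted p values of lists are over the 25 lists of a comparison.

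The genes named follow a rule. Per comparison these are the genes past the threshold with the largest changes (up to 8 per direction) or, since fewer than 3 passed in each direction, the 3 with the smallest p in each direction. To these come, from each list described, the 4 members with the smallest p, of which 3 are given for the root list. Any other gene is said to have been chosen after its values were seen. For a gene below background on every array of 1 group, a lower bound of its fold is given, computed against the dimmest signal called well above background.

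The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were a normexp background correction (offset 50) with quantile normalisation, quantile and cyclic loess normalisation, the deposited workbook in place of the scanner tables, no filter and a filter on all 8 arrays, the mean of a locus's probes, slide as a block, each slide alone, replicate number as a block, leaving out each array in turn, only the 2 groups compared, an intensity trend with robust variance, array weights, other set tests and other thresholds. Chosen after seeing the data were a fit without mock replicate 2 and (+)-borneol replicate 3, a term for these 2 arrays (alone, and with the intensity trend, and in the other set tests), the replicate block with mock replicates 2 and 3 exchanged, keeping spots with outlier flags, and testing all probes one by one.

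The test was tried on simulated data in which a known set of genes was changed. The spread of each gene was taken from these arrays, but the noise was drawn independently between genes and arrays. In the (+)-borneol comparison with mock it found 47.5% of genes changed by 1 log2 unit and 75.2% changed by 2, with 5.8% false calls. In the real arrays, 1 pattern across the arrays held 54.5% of the variation within groups. These shares therefore check the steps only, and do not tell what share of real changes was found. The number of arrays, 2 or 3 per group, limits the precision of each value.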

Results

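Gene expression was measured in Arabidopsis plants given methanol alone (mock) or 1 of the mirror-image forms of borneol, a bicyclic monoterpene alcohol that plants release as a volatile. The labels call the material leaves and elsewhere seedlings, treated 3 days after germination at 23 °C under 16 h light and 8 h dark. Mock and (+)-borneol have 3 arrays each and (-)-borneol has 2. Of 43603 probes, 69.9% to 78.8% lay well above background per array, and the median probe intensity was 337 to 453.6.

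Mock replicate 2 and (+)-borneol replicate 3 stood apart from the other 6 arrays in the genes of the circadian clock. The morning genes CCA1 and LHY encode related transcription factors of the clock's core loop. They were higher in these 2 arrays by 4.07 and 3.52 log2 units than in the other arrays of their own groups. PRR9, a repressor of both genes, was higher by 4.85. The evening genes TOC1, LUX and ELF4 were lower there, at -2.82, -2.79 and -4.12 log2 units. Of these, TOC1 encodes a repressor of the morning genes. PRR7 differed by 0.31 and GI by -0.93. The correlation of the 2 arrays with each other was 0.989, against 0.964 to 0.981 with the other 6. These are correlations across genes, which are not independent replicates. A term for the 2 arrays in the limma model was past the adjusted threshold in 5172 genes. Beyond the clock, the heat shock list lay higher in the 2 arrays by a median of 1.29 log2 units, and the aliphatic glucosinolate, auxin, cell cycle, flavonoid and root lists by 0.83, 0.78, 0.64, 0.61 and 0.56. The xenobiotic list lay lower (-0.96), as did the senescence list (-0.79) and the abscisic acid list (-0.56). The seed storage list (1.36) and the indole glucosinolate and salicylic acid lists (-0.80 and -0.74) also differed, but by mock replicate 2 alone, at 1.97, -1.06 and -0.60 about the mean of the 8 arrays, since (+)-borneol replicate 3 lay at -0.21, -0.04 and -0.09. The clock genes and these lists were chosen for this comparison after the values were seen. Since 1 of the arrays is a mock and the other a (+)-borneol array, several of the values that follow are given also without both arrays or with a term for them.

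**Figure D1:**
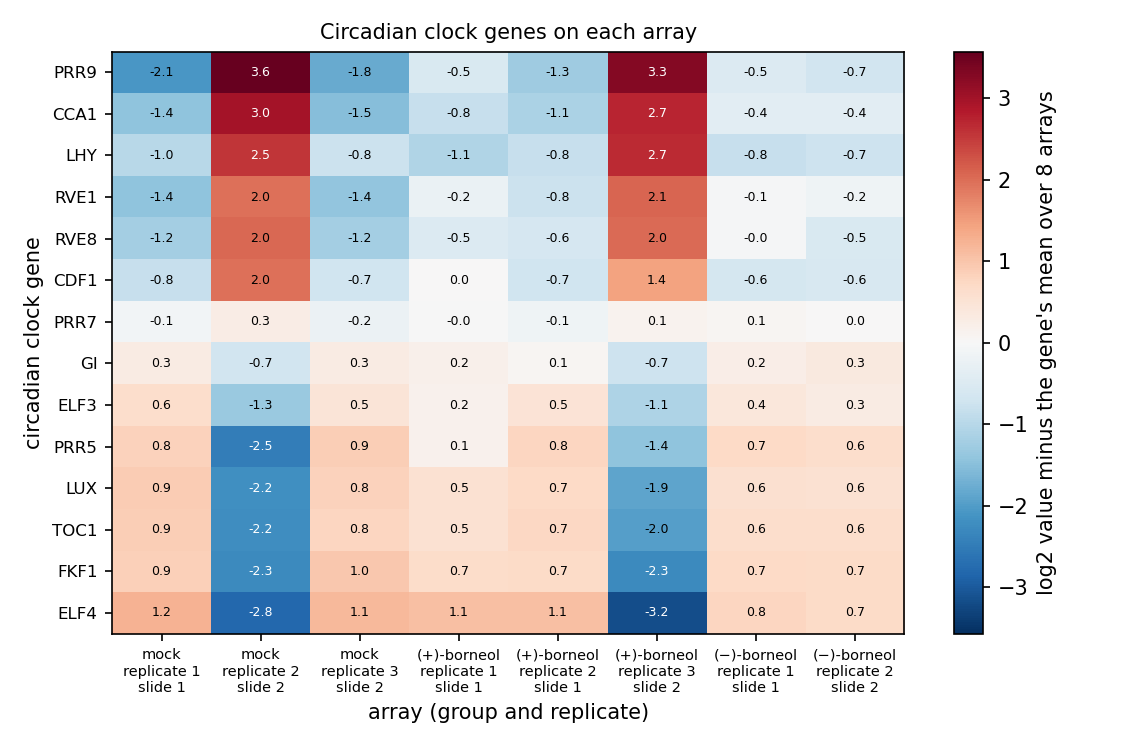
Log2 signal of the 14 clock genes on each of the 8 arrays, relative to the mean of the 8 arrays. Mock replicate 2 and (+)-borneol replicate 3 lie at 2.97 and 2.72 for CCA1, against -1.52 to -0.38 on the other 6 arrays.

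The first comparison, of (+)-borneol with mock, asks which genes respond to (+)-borneol. CYP81D11 (AT3G28740; chromosome 3, probe 10790061 to 10790120), a cytochrome P450 known to be induced by foreign chemicals, had a mean log2 signal of 2.72 ± 0.26 (SD, n = 3) with (+)-borneol and 0.16 ± 0.34 (SD, n = 3) in mock, a 5.91-fold difference. Genes of the xenobiotic response, which modify and export foreign compounds, lay higher as a list, as did mitotic cell cycle genes, flavonoid genes and genes of the unfolded protein response. Expansins and xyloglucan endotransglucosylases, which loosen cell walls, lay lower. These list calls came from camera at its preset correlation, and none passed with an estimated correlation (adjusted p = 0.896). No single gene passed the adjusted threshold.

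CYP81D11 was higher by 2.56 log2 units (SE 0.20, 95% interval 2.07 to 3.05) with the smallest adjusted p of the limma test, 0.16. With slide as a block the difference was 2.49, and within the slides it was 2.56 and 2.35. Within a slide each group has 1 or 2 arrays, and a lone array was assumed to vary like the others. The adjusted p of CYP81D11 was 0.00832 without the 2 arrays that stand apart and 0.00316 with a term for them, and ran from 2.16e-05 to 1 over all alternatives. MLP165 (AT1G35260), a member of the major latex protein family, was higher by 1.14 log2 units (95% interval 0.89 to 1.39), and AT1G34060, annotated as an alliinase family protein, by 1.91 (1.42 to 2.40). Lower were TPX2 (AT1G65970), a thioredoxin-dependent peroxidase, at -2.04 (-2.60 to -1.48), AT5G38710, a putative proline oxidase, at -1.07 (-1.46 to -0.69), and the subtilase gene SBT4.12 at -0.80 (-1.09 to -0.51), whose other probe gave 0.20. None of these 5 genes passed (limma adjusted p 0.188, 0.335, 0.413, 0.706 and 0.706), while TPX2 had an adjusted p of 0.00798 without the 2 arrays, the lowest of its alternatives, which ran to 1.

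The xenobiotic list lay higher by a median of 0.72 log2 units, with 21 of 27 members above 0 (limma camera adjusted p 7.98e-08 at the preset correlation, adjusted p = 0.896 with an estimated correlation). With slide as a block its median was 0.51, and within the slides 0.63 and 0.33. It was 0.60 without the 2 arrays, but without mock replicate 2 alone it was 0.43, with an adjusted p of 0.288 (7.92e-14 to 0.896 over all alternatives). Apart from CYP81D11, which is the 1 member that passed when adjusted over the list alone (p 0.00019), OPR1, an oxophytodienoate reductase, was higher by 1.24 and the glucosyltransferase gene UGT74F2 by 0.53. ABCG40, which encodes a transporter of abscisic acid, differed by -1.40, by -2.03 and -0.52 within the slides, and by -2.08 without the 2 arrays, where it passed (adjusted p 0.0428, with 0.0428 to 1 over all alternatives). The glutathione S-transferase list was not called (median 0.07, adjusted p 0.0877), but 3 members were higher when adjusted over the list alone: GSTU1 by 2.16 (p 0.00489), GSTU2 by 1.58 and GSTU19 by 0.49 (p 0.0486 each).

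All 22 cell cycle genes lay above 0, by a median of 0.29 (adjusted p 3.94e-06 at the preset correlation, adjusted p = 0.896 with an estimated correlation), with no member past the test when adjusted over the list alone. CDKB2;2, a mitotic kinase, was higher by 0.37, the cyclins CYCB2;1 and CYCB2;2 by 0.59 and 0.39, and CDC20.1, an activator of the anaphase-promoting complex, by 0.44. The blocked median was 0.40 and the within-slide medians 0.35 and 0.53. Without (+)-borneol replicate 3 it was 0.14 and missed the threshold (adjusted p 0.0639, with 4.93e-15 to 0.896 over all alternatives), and it was 0.17, 0.55 and 0.18 without mock replicates 1, 2 and 3. The flavonoid list lay higher by 0.31 with 14 of 19 members above 0 (adjusted p 0.00288, adjusted p = 0.896 with an estimated correlation), its blocked median was 0.45 and its within-slide medians were 0.39 and 0.60. PAP1, a transcription factor that switches on anthocyanin synthesis, was higher by 1.66, FLS1 (flavonol synthase) by 0.37, UGT78D1 by 0.25 and GSTF12, which carries anthocyanin to the vacuole, by 0.71, its second probe giving -0.43. The flavonoid call was lost without mock replicate 1 (0.13), mock replicate 3 (0.19) or (+)-borneol replicate 3 (0.13), and the median was 0.63 without mock replicate 2.

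The unfolded protein response list lay higher by 0.11, with 13 of 14 members above 0 (adjusted p 0.00447, adjusted p = 0.896 with an estimated correlation), and by 0.16 with the block and 0.22 and 0.15 within the slides. BIP3, an endoplasmic reticulum chaperone induced by unfolded protein, was higher by 1.14 (95% interval 0.54 to 1.74) and passed when adjusted over the list alone (p 0.0427), and the co-chaperones ERDJ3A and ERDJ3B were higher by 0.79 and 0.30 and the calreticulin gene CRT1A by 0.17. The call was lost without mock replicate 3 (0.08) or (+)-borneol replicate 1 (0.09), and the median was 0.25 without mock replicate 2 and 0.21 without (+)-borneol replicate 2. The wall-loosening list lay lower by a median of -0.18, with 4 of 21 members above 0 (adjusted p 0.00514, adjusted p = 0.896 with an estimated correlation). EXPA5 and EXPA11 were at -0.35 each and EXPA14 and XTH33 at -0.79 each. The median of that list was -0.12 with the block, -0.32 within slide 1 and 0.11 within slide 2, and the call was lost without mock replicate 2 (-0.15) or (+)-borneol replicate 2 (-0.09), while the median was -0.11 without (+)-borneol replicate 1 and -0.31 without (+)-borneol replicate 3. Transposable element genes lay lower by -0.18, with 124 of 369 above 0 (adjusted p 0.0404, adjusted p = 0.896 with an estimated correlation). AT3G43436 was at -0.66, AT3G42280 at -0.77, AT4G37620 at -0.46 and AT4G11200 at 0.28. That median was -0.01 with the block and 0.05 and -0.09 within the slides, and its call was lost without mock replicate 2 (-0.07), mock replicate 3 (-0.10), (+)-borneol replicate 1 (-0.10) or replicate 2 (-0.13), and under normexp (-0.03), quantile (-0.11) and loess (-0.12) normalisation, while the median was -0.39 without mock replicate 1 and -0.30 without (+)-borneol replicate 3.

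The other 19 lists were not called at the preset correlation. Their medians ran from -0.42 for seed storage to 0.28 for root markers. Jasmonate genes were at 0.01, salicylic acid genes at -0.20, indole glucosinolate and camalexin genes at -0.13, photosynthesis genes at 0.00 and terpene genes at 0.01. Median and mean differed in sign for the oxidative stress (0.07 and -0.15), abscisic acid and cold (-0.05 and 0.06), heat shock (-0.07 and 0.04) and lipid reserve (0.01 and -0.02) lists. By limma, 0 of 22748 genes passed. An unadjusted p under 0.05 was found for 1004 (481 higher, 523 lower), where evenly spread chance p values would give 1137. Camera with an estimated correlation and the directional test of fry called 0 lists. The mixed test of fry, which ignores direction, passed for the xenobiotic and glutathione S-transferase lists (adjusted p 0.0378 each). Without mock replicate 2 the count of genes that passed was 44 (7 higher, 37 lower), and without both arrays that stand apart it was 70 (19 higher, 51 lower). The count at an unadjusted p under 0.05 was 677 without mock replicate 1, 2984 without mock replicate 2 and 3848 without both arrays. It thus moved to either side of 1137 with the arrays left in, and does not show the absence of an effect.

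**Figure D2:**
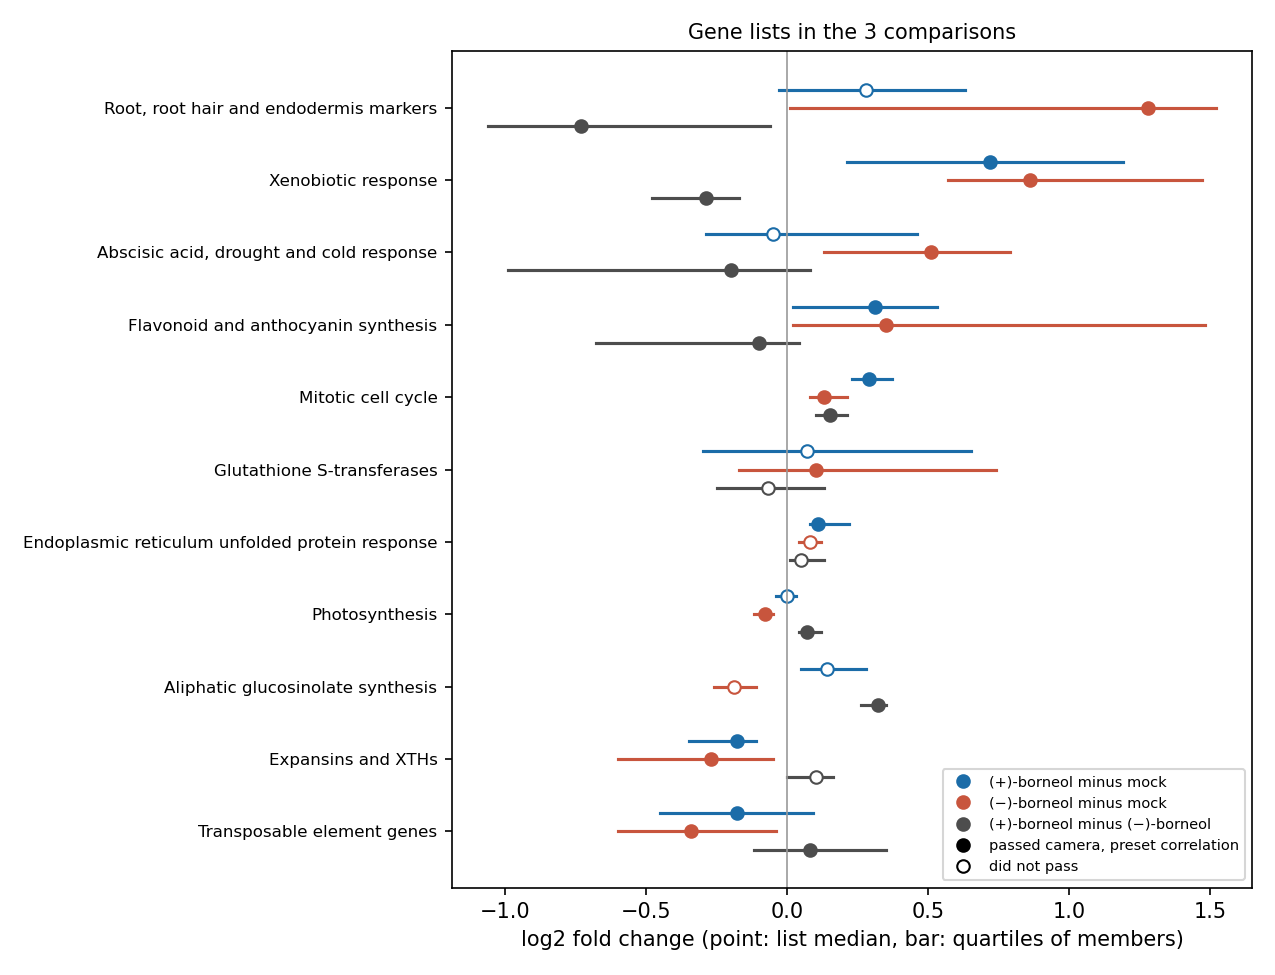
Median log2 difference (points; filled where limma camera passed at the preset correlation, none of which passed with an estimated correlation) and quartiles of members (bars) of the gene lists called in at least 1 comparison, and their values in all 3. The xenobiotic list lies at 0.72 for (+)-borneol and 0.86 for (-)-borneol against mock, and the photosynthesis list at -0.08 for (-)-borneol, or 0.00 under cyclic loess.

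The second comparison, of (-)-borneol with mock, asks the same of the mirror image. CYP81D11 was again the gene with the smallest p among those higher, at a mean of 2.72 ± 0.05 (SD, n = 2) against 0.16 ± 0.34 (SD, n = 3) in mock. The xenobiotic, flavonoid, root marker and abscisic acid lists lay higher, and so, by less, did glutathione S-transferases and cell cycle genes. Wall-loosening genes, transposable element genes and photosynthesis genes lay lower. None of these 9 lists passed with an estimated correlation (adjusted p = 0.751 to 0.915). Again no single gene passed the adjusted threshold.

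CYP81D11 was higher by 2.57 log2 units (SE 0.23, 95% interval 2.02 to 3.11; limma adjusted p 0.205), and by 2.53 with slide as a block and 2.39 and 2.67 within the slides. Its adjusted p was 0.0317 without the 2 arrays that stand apart and 0.0112 with a term for them, and ran from 0.000125 to 1 over all alternatives. MLP165 was higher by 1.18 (0.90 to 1.46) and AT1G34060 by 2.12 (1.57 to 2.66). The proline oxidase gene AT5G38710 was lower, at -1.86 (-2.30 to -1.43; adjusted p 0.205, and 0.0433 without the 2 arrays, with 0.0186 to 1 over all alternatives). AT3G25490, a putative wall-associated kinase, and AT4G07526, of unknown function, were below background in both (-)-borneol arrays, and so at least 1.42-fold and at least 1.34-fold lower (adjusted p 0.617 each).

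The xenobiotic list lay higher by a median of 0.86, with 25 of 27 members above 0 (limma camera adjusted p 1.05e-13, adjusted p = 0.751 with an estimated correlation). Its median was 0.79 with the block, 0.60 and 1.33 within the slides, 0.56 without mock replicate 2 and 1.31 without mock replicate 3. OPR1 was higher by 1.46 and the glucosyltransferase genes UGT73B1 and UGT74F2 by 1.2 and 0.56, the first by 0.88 without the 2 arrays that stand apart (adjusted p 0.044, with 0.0194 to 1 over all alternatives). CYP81D11 passed when adjusted over the list alone (p 0.000383). The glutathione S-transferase list lay higher by 0.10, with 19 of 31 members above 0 (adjusted p 0.0288, adjusted p = 0.751 with an estimated correlation). Its median was 0.02 with the block and -0.01 and 0.14 within the slides, and its call was lost without mock replicate 2 (0.07) or (-)-borneol replicate 2 (0.07), while the median was 0.16 without mock replicate 3, 0.17 with loess and 0.02 with normexp. GSTU1 was higher by 2.03 (95% interval 1.27 to 2.79) and passed when adjusted over the list alone (p 0.014), and over all genes without the 2 arrays (1.83, adjusted p 0.034) or with a term for them (adjusted p 0.0359, with 0.00238 to 1 over all alternatives). GSTU25 was higher by 2.92, GSTU2 by 1.65 and GSTU19 by 0.56.

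The flavonoid list lay higher by 0.35, with 15 of 19 members above 0 (adjusted p 3.25e-06, adjusted p = 0.751 with an estimated correlation), and 6 members passed when adjusted over the list alone. Among these, PAP1 was higher by 2.09, GSTF12 by 1.59 (0.07 on its second probe), FLS1 by 0.48 and MYB12, a regulator of flavonol synthesis, by 1.25. GSTF12 passed over all genes without the 2 arrays that stand apart (1.96, adjusted p 0.034) and with a term for them (adjusted p 0.0481, with 0.00546 to 1 over all alternatives). The median was 0.46 with the block, 0.76 and 0.21 within the slides, 0.71 without mock replicate 2, 0.21 without mock replicate 1 and 0.23 without mock replicate 3. The root list lay higher by 1.28, with 8 of 11 members above 0 (adjusted p 9.3e-05, adjusted p = 0.751 with an estimated correlation). Its median was 1.42 with the block, 1.98 and 0.87 within the slides and 0.85 without mock replicate 1, 0.52 with normexp, and 0.17 over genes well above background on all 8 arrays. The root hair expansin gene EXPA7 was below background in mock and at least 5.07-fold higher, COBL9, needed for root hair growth, was higher by 1.55, and EXPA18, another root hair expansin, by 1.68. These 3 passed when adjusted over the list alone.

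The abscisic acid, drought and cold list lay higher by 0.51, with 22 of 26 members above 0 (adjusted p 0.012, adjusted p = 0.827 with an estimated correlation). NCED3, which makes the precursor of abscisic acid, was higher by 0.83, the drought-induced transcription factor genes RD26 and HB7 by 0.96 and 0.58, and HAI2, a phosphatase of the pathway that was below background in mock, was at least 2.81-fold higher. The median of that list was 0.42 with the block and 0.15 and 0.56 within the slides, 0.11 without mock replicate 2, and 0.02, with the call lost, under a term for the arrays that stand apart. The cell cycle list lay higher by 0.13, with 22 of 22 members above 0 (adjusted p 0.0348, adjusted p = 0.915 with an estimated correlation): CYCB2;2 by 0.31, CYCB2;3 by 0.29, CDKB2;2 by 0.24 and CDC20.1 by 0.22. The cell cycle median was 0.19 with the block and 0.43 and 0.00 within the slides. Its call was lost without mock replicate 1 (0.01), mock replicate 3 (-0.02), (+)-borneol replicate 1 (0.13), (-)-borneol replicate 1 (0.13) or (-)-borneol replicate 2 (0.17), and under quantile (adjusted p 0.0702) and loess (adjusted p 0.0612) normalisation, and the median was 0.42 without mock replicate 2.

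The wall-loosening list lay lower by -0.27, with 4 of 21 members above 0 (adjusted p 0.000275, adjusted p = 0.751 with an estimated correlation), by -0.30 with the block and by -0.21 and -0.35 within the slides. XTH33 was at -0.95, XTH22, also known as the touch-induced TCH4, at -0.72, EXPA11 at -0.48 and EXPA5 at -0.27. Under a term for the arrays that stand apart its adjusted p was 0.0587 (3.11e-05 to 0.751 over all alternatives). Transposable element genes lay lower by -0.34, with 79 of 369 above 0 (adjusted p 9.3e-05, adjusted p = 0.827 with an estimated correlation). The median was -0.20 with the block and -0.13 and -0.28 within the slides. It was -0.56, -0.16 and -0.22 without mock replicates 1, 2 and 3, -0.55 without (-)-borneol replicate 2, -0.06 with normexp and -0.20 with quantile normalisation, and -0.05, with the call lost, without (-)-borneol replicate 1. AT2G16140, AT2G07683 and AT5G34843 were below background in (-)-borneol and at least 1.19-fold, 1.42-fold and 1.15-fold lower, and AT3G21030 was at 0.36. The photosynthesis list lay lower by -0.08, with 1 of 35 members above 0 (adjusted p 0.0136, adjusted p = 0.837 with an estimated correlation), but the call was lost under normexp (-0.01), quantile (-0.02) and cyclic loess normalisation (0.00, with the other direction of the test). PETC, of the cytochrome complex, was at -0.26, RCA (Rubisco activase) at -0.17, PSAN at -0.16 and LHCB4.1 at -0.10. The photosynthesis median was -0.08 with the block and -0.03 and -0.10 within the slides, and its call was lost without mock replicate 2 (-0.03) or (-)-borneol replicate 2 (-0.09).

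The other 16 lists were not called, with medians from -0.41 for seed storage to 0.25 for the clock. For the clock, the directional test of fry gave an adjusted p of 0.0756, or 0.047 without both arrays that stand apart and 0.0329 with a term for them. About the mean of all arrays, CCA1 lay at -0.39 and -0.38 in (-)-borneol and at -1.43 and -1.52 in mock replicates 1 and 3. PRR9 also lay nearer the arrays that stand apart (-0.49 and -0.67 against -2.08 and -1.81). LHY differed less (-0.81 and -0.74 against -0.99 and -0.78). These genes were chosen after their values were seen. In the jasmonate list (0.04), the defensin gene PDF1.2 was at least 2.48-fold lower, being below background in (-)-borneol, and passed when adjusted over the list alone (p 0.0381). Median and mean differed in sign for the pattern-triggered defence (0.14 and -0.01), indole glucosinolate (-0.03 and 0.01) and DNA damage (-0.10 and 0.01) lists, and the camera direction differed from the median's for the oxidative stress (-0.03) and jasmonate lists. By limma, 0 genes passed and 1205 had an unadjusted p under 0.05 (684 higher, 521 lower), where evenly spread chance p values would give 1137. Camera with an estimated correlation and either test of fry called 0 lists. Without mock replicate 2 the count was 9 genes, without (+)-borneol replicate 2 it was 7, and without both arrays that stand apart it was 51 (27 higher, 24 lower). Array weights, which gave mock replicate 2 a weight of 0.17 and (+)-borneol replicate 3 a weight of 0.31, gave 336. The count at an unadjusted p under 0.05 was 1008 without mock replicate 1, 1931 without mock replicate 2 and 3657 without both arrays that stand apart. It thus moved to either side of 1137 with the arrays left in.

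**Figure D3:**
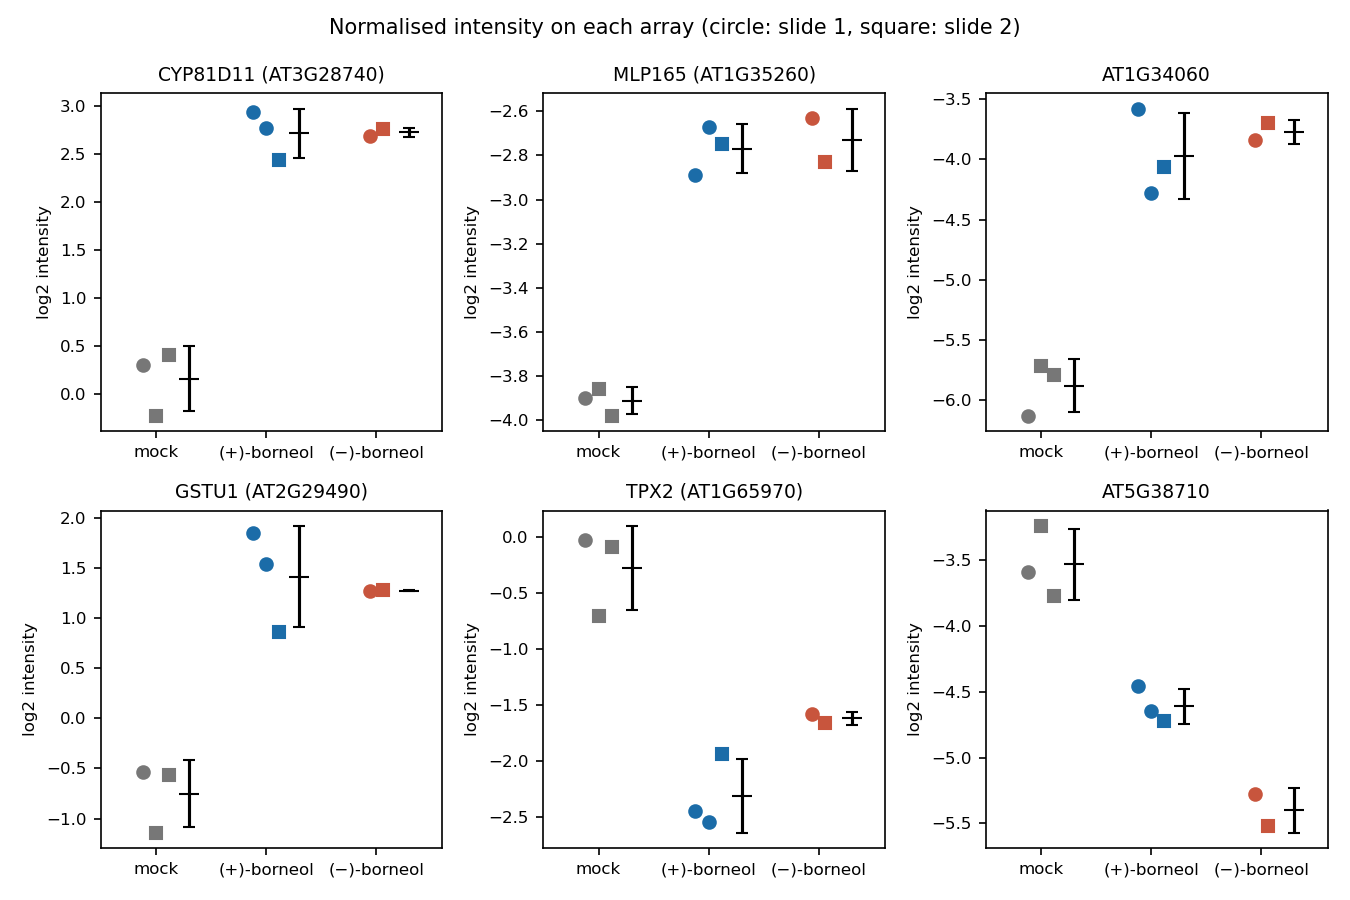
Log2 intensity relative to the array's 75th percentile of 6 genes on each array (circles slide 1, squares slide 2), by group, with the group mean and SD. For CYP81D11 the means are 2.72 with either borneol and 0.16 in mock.

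The third comparison sets (+)-borneol against (-)-borneol, which have the same atoms and bonds and differ as mirror images, at the same dose and time. CYP81D11 differed between them by -0.01 log2 units (95% interval -0.55 to 0.54), MLP165 by -0.04 (-0.32 to 0.24) and AT1G34060 by -0.21 (-0.75 to 0.34). A p that misses the threshold does not show that they act alike. Root marker genes lay lower with (+)-borneol than with (-)-borneol, as did xenobiotic, flavonoid and abscisic acid genes, and aliphatic glucosinolate and cell cycle genes lay higher. None of these lists passed with an estimated correlation (adjusted p = 0.726), and without (+)-borneol replicate 3 the xenobiotic median was -0.02 and the direction turned for the abscisic acid, aliphatic glucosinolate and cell cycle lists. No gene passed the adjusted threshold.

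PDF1.2 (AT5G44420), a defensin gene induced by jasmonate with ethylene, was at least 2.82-fold higher with (+)-borneol, being below background in (-)-borneol (limma adjusted p 1). It passed when adjusted over the jasmonate list alone (p 0.0223), a list whose median was -0.05 and mean 0.01. AT1G31163, related to F-box proteins, was higher by 1.19 (0.62 to 1.76) and AT1G77640, a putative AP2 transcription factor, by 0.64 (0.29 to 0.98). Lower with (+)-borneol were AT2G39530, a putative membrane protein, at -1.61 (-2.04 to -1.17), AT2G31425, annotated as an inhibitor of pectinesterase, at -1.50 (-2.06 to -0.93), and AT1G17960, a putative threonyl-tRNA synthetase, at -2.00 (-2.75 to -1.24). All 6 had an adjusted p of 1.

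The root list lay lower in (+)-borneol by -0.73, with 3 of 11 members above 0 (limma camera adjusted p 0.00047, adjusted p = 0.726 with an estimated correlation). COBL9 was at -1.27 (-2.16 to -0.38), EXPA18 at -1.45 (-2.64 to -0.25) and EXPA7 at -1.63 (-3.26 to 0.00). The root median was -0.56 with the block, -0.84 and -0.16 within the slides, -0.16 without (+)-borneol replicate 1, -0.23 with normexp, and -0.06 over genes well above background on all 8 arrays. The flavonoid list lay lower by -0.10, with 6 of 19 members above 0 (adjusted p 0.00232, adjusted p = 0.726 with an estimated correlation). Named members were UGT79B1 and 5MAT, which decorate anthocyanins, at -1.10 (-2.35 to 0.15) and -0.95 (-2.01 to 0.11), GSTF12 at -0.88 (-1.79 to 0.04) and MYB12 at -0.74 (-1.57 to 0.10). The flavonoid median was -0.12 with the block and -0.31 and 0.04 within the slides, -0.35 without (+)-borneol replicate 3, -0.17 and -0.24 without (-)-borneol replicates 1 and 2, and -0.11, with the call lost, without (+)-borneol replicate 2.

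For 4 other lists the direction of the median or of the test turned without (+)-borneol replicate 3, 1 of the arrays that stand apart. Aliphatic glucosinolate genes lay higher by 0.32, with 16 of 17 above 0 (adjusted p 0.00056, adjusted p = 0.726 with an estimated correlation), with AOP2 higher by 0.98, FMOGSOX1 by 0.63, the regulator MYB28 by 0.27 and SUR1 by 0.26, the last 3 by 0.28, 0.09 and 0.06 without the 2 arrays that stand apart. The median was -0.01 without (+)-borneol replicate 3, 0.53 without (+)-borneol replicate 2, 0.40 with the block and -0.04 and 1.03 within the slides. The cell cycle list lay higher by 0.15, with 22 of 22 above 0 (adjusted p 0.014, adjusted p = 0.726 with an estimated correlation), with CYCB2;1 at 0.37, the Aurora kinase genes AUR1 and AUR2 at 0.24 and 0.23 and CDC20.1 at 0.22, and these 4 at 0.13, 0.13, 0.12 and 0.11 without the 2 arrays. This median was 0.01, with the other direction of the test, without (+)-borneol replicate 3, 0.24 without (+)-borneol replicate 1 or replicate 2, and 0.14, with the call lost, without (-)-borneol replicate 2. With the block it was 0.20 and within the slides -0.01 and 0.49. The abscisic acid and cold list lay lower by -0.20, with 8 of 26 above 0 (adjusted p 0.04, adjusted p = 0.726 with an estimated correlation), with CBF1 and CBF2, which switch on cold-response genes, at -1.05 and -0.47, HAI2 at -1.11 and ABI1 at -0.19. Without the 2 arrays CBF1 was at -0.5, HAI2 at -0.01 and ABI1 at -0.06, while CBF2 was at -0.6. The median was 0.06 without (+)-borneol replicate 3 and -0.41 without (+)-borneol replicate 1, and the call was lost without (+)-borneol replicate 2 (-0.27), (-)-borneol replicate 1 (-0.30) or (-)-borneol replicate 2 (-0.24) and under cyclic loess (-0.24). With the block it was -0.24 and within the slides 0.14 and -0.80. Transposable element genes lay higher by 0.08, with 228 of 369 above 0 (adjusted p 0.0196, adjusted p = 0.726 with an estimated correlation), with AT5G35420 at 1.02, AT5G31758 at 0.46 and AT3G17050 at 0.55, and AT5G45595 at least 1.18-fold higher. This median was -0.06 without (+)-borneol replicate 3, -0.09 without (-)-borneol replicate 1, 0.31 without (-)-borneol replicate 2, 0.18 and 0.17 without (+)-borneol replicates 1 and 2, 0.03 and 0.07, with the call lost, under normexp and quantile normalisation, 0.17 with the block and 0.11 and 0.21 within the slides.

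The xenobiotic list lay lower by -0.29, with 3 of 27 above 0 (adjusted p 0.00209, adjusted p = 0.726 with an estimated correlation), but by only -0.02, with the call lost, without (+)-borneol replicate 3 and by -0.51 without (+)-borneol replicate 1. DTX3, a membrane exporter, was at -2.12 (-3.71 to -0.53), CYP710A1, a sterol desaturase, at -1.38, and the transporter genes ABCG40 and ABCC3 at -0.80 and -0.62, or -1.18 and -0.4 without the 2 arrays that stand apart, where CYP710A1 was at -1.07. Its median was -0.37 with the block and 0.03 and -0.86 within the slides. It turned to 0.1 with a term for the 2 arrays that stand apart (camera adjusted p 0.606) and with the workbook's replicate numbers as a block (0.557). Under these numbers the deviations of the (+)-borneol and mock arrays of each pair correlated at 0.29, 0.27 and 0.58. The last is the pair that stands apart, which also shapes the other 2 values, as deviations within a group sum to 0. (+)-borneol replicate 2 and (-)-borneol replicate 2 correlated at -0.16. The block by these numbers called 3 lists between the borneols, against 8 without it. The photosynthesis list lay higher by 0.07, with 33 of 35 above 0 (adjusted p 0.00253, adjusted p = 0.726 with an estimated correlation), but the call was lost under normexp (0.02), quantile (0.01) and cyclic loess normalisation (-0.02). RCA was at 0.18, PETC at 0.15, RBCS3B at 0.13 and LHCB5 at 0.13, the last at -0.01 with normexp. The photosynthesis median was 0.08 with the block and 0.07 within either slide, 0.12 without (+)-borneol replicate 2, and its call was lost without (+)-borneol replicate 1 (0.02) or (-)-borneol replicate 2 (0.06). The other 17 lists were not called, with medians from -0.25 for the clock to 0.26 for seed storage. By limma, 0 genes passed and 342 had an unadjusted p under 0.05 (148 higher, 194 lower), where evenly spread chance p values would give 1137. Camera with an estimated correlation and either test of fry called 0 lists. Without (+)-borneol replicate 2 the count of genes that passed was 6, all lower in (+)-borneol. The count at an unadjusted p under 0.05 was 288 without mock replicate 3, 700 without mock replicate 2 and 1472 without both arrays that stand apart. It thus moved to either side of 1137 with the arrays left in, and does not show the absence of an effect.

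The differences of the 2 borneols from mock were then compared across genes. Pearson's r over the 22748 genes was 0.624, and genes are not independent replicates. Both share the mock arrays, and simulated unchanged groups against those arrays gave 0.446. The simulation drew arrays and genes as independent, so its values here leave out shifts shared by some arrays or by many genes. The covariance was 0.0933 against a simulated 0.0725, and 73.8% of genes had the same sign against 64.7%. Without the 2 arrays that stand apart r was 0.666 (simulated 0.501) and the covariance 0.141 (simulated 0.0623). With a term for them r was 0.615 (simulated 0.429). Within slide 1 and slide 2 the observed r was 0.69 and 0.158, and with slide as a block 0.54. It was 0.394 without (+)-borneol replicate 2 and 0.739 without mock replicate 1. At an unadjusted p under 0.05, 261 genes were higher in both, where simulated unchanged groups against the same mock arrays shared 144, and 245 were lower in both, against a simulated 140.8. The mock arrays cannot be split into parts of at least 2. Slide, with group in the model, was past the adjusted threshold in 406 genes, in 14 and 214 without mock replicates 1 and 3, in 195, 168 and 0 without (+)-borneol replicates 1, 2 and 3, and in 141 without either (-)-borneol array.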

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

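Of the tests in this part, those of slide, of the time of harvest, of the arrays behind the xenobiotic and root lists, of root tissue and of the 2 arrays' deviations were chosen only after the result was seen. The slope for a label swap was set down before its value was seen but after the 2 arrays were seen to stand apart, and other splits of the arrays were chosen before.

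On (+)-borneol replicate 1 the spike-in control probes, which belong to no plant gene and were used in no comparison, had a median intensity of 98770, against 595.6 to 980.7 on the other 7 arrays, and lay 5.53 log2 units above their mean in mock.

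Mock replicate 2 and (+)-borneol replicate 3 stood apart from the other 6 arrays. Against the other arrays of their own groups, PRR9 was higher by 4.85 log2 units, CCA1 by 4.07, and ELF4 was at -4.12. Both lie on slide 2, but over the 5172 genes called for the pair the slide difference of the other arrays followed the pair's difference with a slope of 0.03 in (-)-borneol and 0.05 in mock, where slide as the cause needs a slope near 1. Whether their labels were swapped stays open. Both deviate from their groups the same way (correlation 0.58 across genes), but a shift shared by both arrays gives this with or without a swap. Over the 70 genes called in (+)-borneol against mock without them, their difference followed that of the others with a slope of -0.08. A swap needs a slope near -1 and right labels a slope near 1, so the slope is far from both. Its 95% interval (-0.27 to 0.12) is over genes, which are not independent replicates. A candidate explanation is that both samples were harvested at another time of day, since the clock genes differed by a median size of 2.86 log2 units, at percentile 100 of 10000 random lists matched on expression (highest 0.89). This is a hypothesis from the same data, the labels give no time of harvest, and a difference in age or growth conditions was not tested.

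The xenobiotic list lay higher than mock with both borneols, by medians of 0.72 and 0.86. Without both arrays that stand apart the lower of the medians was 0.56, which argues against this pair as the whole cause of the direction. Without mock replicate 2 alone the (+)-borneol median was 0.43 and its camera call was lost (adjusted p 0.288). The lower of the medians with slide as a block was 0.51, which argues against slide as the whole cause of the direction. The (+)-borneol median without the array with bright spike-in probes was 0.48, which argues the same for that array. All but the 0.43 passed camera at the preset correlation of 0.01, where the list's estimated correlation was 0.715. With an estimated correlation the adjusted p without both arrays was 0.418 and 0.305. The directional test of fry, for (+)- and (-)-borneol, gave adjusted p values of 0.794 and 0.632 with all arrays. Its values were 0.0543 and 0.0251 without both arrays, and 0.0324 and 0.0329 with a term for them. The outcome thus depends on the set test and on these arrays, so the calls themselves do not decide about a cause. A response to either borneol may account for the list, as a hypothesis only. Over all arrays the adjusted p with an estimated correlation was 0.896 and 0.751, and the median of 0.48 rests on 2 (+)-borneol arrays.

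The root list lay lower with (+)-borneol than with (-)-borneol, by a median of -0.73. The pair of arrays that stands apart is argued against as the cause of the direction, since the median without both was -1.03. That median passed camera at the preset correlation of 0.01, where the list's estimated correlation was 0.528. With an estimated correlation the adjusted p was 0.558 without both arrays and 0.726 over all arrays, so the call itself does not decide about a cause. A larger share of root tissue in the (-)-borneol samples stays open, as it would move all root markers alike, and of the 7 markers well above background on every array 2 had a 95% interval that lies above the list's median, LRX1 (0.03, -0.45 to 0.51) and CASP2 (0.05, -0.56 to 0.65), too few to decide. Slide as the whole cause of the direction is argued against, since both groups lie on both slides and the median with slide as a block was -0.56. That median passed camera at the preset correlation (adjusted p 0.00683, with 2.06e-07 to 0.876 over all alternatives). Open too are a difference in how the mirror images act, as a hypothesis only, and the weight of (+)-borneol replicate 1, the array with bright spike-in probes, since the median was -0.16 without it (adjusted p 0.013), -0.84 within slide 1 and -0.16 within slide 2, where 1 array stands against 1, and -0.23 with normexp.

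The 6 arrays of (+)-borneol and mock make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 0 genes, which all 10 splits reach, and the highest other split called 189. For lists the real split called 6 and the highest other split 16, with 8 splits at 6 or more. The split with 189 genes puts mock replicate 2 and (+)-borneol replicate 3 on 1 side, so it points to a structure of the samples, although 2 other splits that do so called 0 and 1. The split that follows slide called 46 and also puts these 2 arrays together, so it does not single out slide, and with slide as a block the real count was again 0. For slide, 2 of the 35 splits of 8 arrays into 4 and 4 gave as many genes as the real 406, the real one included, so chance is not excluded. The highest other split, at 5172 genes, has these 2 arrays and both (-)-borneol arrays on 1 side. With group in the model it is the same fit as the term for the 2 arrays. It is thus no further evidence of a structure and no chance regrouping either, so the share of splits does not decide about slide.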

How the results depend on the processing

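The fits without mock replicate 2 and (+)-borneol replicate 3 or with a term for them, the exchanged replicate block, kept outlier spots and probe-by-probe tests were chosen only after the result was seen. By limma, 0 genes passed in the 3 comparisons under quantile or loess scaling, the deposited workbook, either other filter, the mean of probes, slide as a block, each slide alone, the replicate block and kept outlier spots. Over 23 called lists, 492 of 667 values under alternatives kept direction and call, 138 kept direction only and 37 turned, and 10 lists never turned. Over 108 values of named genes, 2840 of 2896 kept direction and side of the threshold, 55 came to pass it and 1 turned. Signal over background limits the root list, 7 of whose 11 genes lie above background on every array. Where a value differs below, the cause was not tested unless fewer arrays or another test are named.

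The genes called for (+)-borneol against mock numbered 1 with normexp, 1 with the intensity trend, 2 with array weights, and 166 at an unadjusted p under 0.05 and at least 2-fold. For (-)-borneol against mock they numbered 22 in the fit of these 2 groups only and 336 with array weights. Leaving out 1 array gave 0 to 44 genes for (+)-borneol, 0 to 9 for (-)-borneol and 0 to 6 between the borneols, with 44 and 9 reached without mock replicate 2 and 6 without (+)-borneol replicate 2. Lists called ran from 4 to 11, 6 to 14 and 4 to 12. The correlation of effects ran from 0.394 to 0.739, and was 0.158 within slide 2, with fewer arrays.

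Genes called for slide numbered 0 with normexp, 66 with quantile and 53 with loess scaling, 45 over genes above background on all arrays, 0 with the intensity trend, 906 with array weights, 1005 over all probes, and 0 to 278 when 1 array was left out.

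Without mock replicate 2 and (+)-borneol replicate 3 the counts were 70 and 51 genes for (+)- and (-)-borneol, 11 lists for (+)-borneol and 0 genes for slide. With a term for them they were 4 and 16 genes, 3 lists between the borneols and 46 genes for slide, and with the intensity trend added 69 and 113 genes, 3 lists and 0 genes for slide. Within slide 1, with 1 mock and 1 (-)-borneol array assumed to vary like the others, 11 lists were called for (+)-borneol and 4 between the borneols, and array weights gave 11 for (+)-borneol.

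With an estimated correlation camera called 0 lists in every comparison, with all arrays, without those 2 arrays and with a term for them. The directional test of fry called 0, 0 and 0 lists with all arrays, 5, 8 and 2 without the 2 arrays, and 3, 5 and 0 with the term. Without the 2 arrays it called the cell cycle, flavonoid, indole glucosinolate, ethylene and pattern-triggered defence lists for both borneols. For (-)-borneol the xenobiotic, senescence and clock lists came to these. With the term it called the cell cycle, glutathione S-transferase and xenobiotic lists for both borneols, and the flavonoid and clock lists for (-)-borneol.

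Lists turned as follows between the borneols. Transposable element genes were at -0.11 without a filter, -0.06 without the 2 arrays and -0.03 with the term, alone or with the trend. Aliphatic glucosinolate genes were at -0.04 within slide 1 and -0.01 without the 2 arrays. Cell cycle genes were at -0.01 within slide 1, 0.01 without the 2 arrays and -0.05 with the term, alone or with the trend. Abscisic acid genes were at 0.14 within slide 1, 0.06 without the 2 arrays and -0.04 with the term, alone or with the trend, where the test turned. Xenobiotic genes were at 0.03 within slide 1 and 0.10 with the term, alone or with the trend. Flavonoid genes were at 0.04 within slide 2. Photosynthesis genes were at -0.02 with loess, and LHCB5 was at -0.01 with normexp. Leaving out 1 array gave -0.01 to 0.53 for aliphatic glucosinolate, 0.01 to 0.24 for cell cycle, -0.09 to 0.31 for transposable element and -0.41 to 0.06 for abscisic acid genes. Against mock, transposable element genes were at 0.05 within slide 1 and wall genes at 0.11 within slide 2 for (+)-borneol. For (-)-borneol, glutathione S-transferases were at -0.01 within slide 1, photosynthesis genes at 0.00 with loess, abscisic acid genes at 0.02 with the term, alone or with the trend, and cell cycle genes at -0.02 to 0.42 when 1 array was left out.

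The replicate numbers of the scanner tables do not pair the arrays: deviations from the group means correlated at 0.29, -0.51 and -0.21 between mock and (+)-borneol arrays of the same number. With the replicate number as a block, 0, 0 and 0 genes and 6, 8 and 6 lists were called, the correlation of effects was 0.545, and transposable element genes were at -0.02 between the borneols. With mock replicates 2 and 3 exchanged, as the workbook names them, those correlations were 0.29, 0.27 and 0.58, a hint from the data only. The last is the pair that stands apart, which also shapes the other 2 values, as deviations within a group sum to 0. In this block (-)-borneol replicate 1 correlated at 0.35 with mock and 0.19 with (+)-borneol, and replicate 2 at 0.21 and -0.16. That block called 1, 0 and 0 genes and 3 lists between the borneols, where cell cycle, transposable element and abscisic acid genes were at -0.05, -0.03 and -0.04 and xenobiotic genes at 0.10, and abscisic acid genes at 0.02 for (-)-borneol against mock.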

Other observations

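The fits in this part without mock replicate 2 and (+)-borneol replicate 3, or with a term for them, were chosen only after the result was seen, as were the genes named in it. Without these 2 arrays, 2 arrays per group remained, and some genes tied to defence lay lower with both borneols. PAD3, which makes the last step of the phytoalexin camalexin, fell by 1.94 log2 units with (+)-borneol and by 1.79 with (-)-borneol, PBS3, needed for salicylic acid synthesis, by 2.27 and 1.99, and PROPEP3, the precursor of a danger peptide, by 3.21 and 2.43. ACS2, of ethylene synthesis, fell by 3.62 and CYP71A12, of camalexin synthesis, by 2.04 with (+)-borneol. The indole glucosinolate and camalexin list lay lower by medians of -0.49 and -0.29 (limma camera adjusted p 9.01e-08 and 1.64e-05 at the preset correlation, adjusted p = 0.105 and 0.126 with an estimated correlation), the salicylic acid list by -0.39 and -0.35 (adjusted p 0.00113 and 0.000508, adjusted p = 0.418 and 0.512 with an estimated correlation) and the ethylene list by -0.41 and -0.20 (adjusted p 0.00038 and 0.00473, adjusted p = 0.118 and 0.253 with an estimated correlation). In this fit the directional test of fry called the indole glucosinolate list (adjusted p 0.00114 and 0.0111) and the ethylene list (0.0114 and 0.0369). It did not call the salicylic acid list (0.0594 and 0.0612). With a term for the 2 arrays fry called none of the 3 for (+)-borneol (indole 0.892, salicylic acid 0.969, ethylene 0.788) or (-)-borneol (0.714, 0.676 and 0.676). Of the 51 genes lower with (+)-borneol without the 2 arrays, 21 were also lower in the (+)-borneol array left out than in the mock array left out. Between these 2 arrays PBS3 differed by -0.45 and ACS2 by -0.11, while PAD3 (0.51), PROPEP3 (1.5) and CYP71A12 (3.1) went the other way. The list medians of these 2 arrays also went the other way, with mock replicate 2 at -1.06, -0.60 and -0.15 about the mean of the 8 arrays and (+)-borneol replicate 3 at -0.04, -0.09 and 0.04 for the indole glucosinolate, salicylic acid and ethylene lists. With a term for the 2 arrays none of the 3 lists was called for (+)-borneol (adjusted p 0.222, 0.331 and 0.232 at the preset correlation, adjusted p = 0.994 each with an estimated correlation) or for (-)-borneol (adjusted p 0.177, 0.0796 and 0.177), so the shift rests on leaving these arrays out. The jasmonate list was not called without the 2 arrays (medians 0.02 and -0.06, adjusted p 0.888 and 0.731 at the preset correlation).

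In the same fit, 5 genes of anthocyanin synthesis and transport rose with (-)-borneol, which does not make a test of the pathway: DFR by 2.04 log2 units, LDOX by 2.11, UGT79B1 by 2.34, 5MAT by 1.86 and GSTF12 by 1.96 (its second probe gave 0.07 with all arrays). The flavonoid list, which holds them, had a median of 0.71 in this fit (camera adjusted p 1.08e-10 at the preset correlation, 0.0633 with an estimated correlation). The directional test of fry called this list higher with (-)-borneol (adjusted p 0.000313) and with (+)-borneol (0.00114). Between the borneols fry called it lower with (+)-borneol (0.00767). With a term for the 2 arrays the fry adjusted p was 0.0138, 0.0789 and 0.0942 in the same order. With (+)-borneol none of these 5 passed, and the difference between the borneols did not pass either (DFR at -1.45, adjusted p 0.187). The starch synthase gene GBSS1 rose by 1.53 and the sugar transporter gene SWEET13 by 1.59. With (+)-borneol, GSTU1 rose by 2.25, and with (-)-borneol by 1.83. The drought-protective protein gene LEA7 was higher by 3.29 with (+)-borneol, but lower by 3.16 in the (+)-borneol array left out than in the mock array left out, and 11 of the 19 genes higher with (+)-borneol were also higher there. Of the genes called in each comparison, 9 were higher in both (of 19 and 27) and 19 lower in both (of 51 and 24). The mock arrays are shared. Simulated unchanged groups shared 0, which was set in advance, as unchanged genes hardly pass an adjusted threshold. At an unadjusted p under 0.05, 1224 were higher and 920 lower in both, against a simulated 181.4 and 181.5. The simulation drew the noise of each gene on its own, without shifts shared by many genes, so it does not show how far such counts vary. With a term for the 2 arrays in place of leaving them out, 4 genes passed for (+)-borneol and 16 for (-)-borneol.

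Simulated groups gave a correlation of effects of 0.446 with no change, against the observed 0.624. Of 560 ways to regroup the 8 arrays into 3, 3 and 2, 100 were drawn. Their correlations ran from -0.08 to 0.878 with a median of 0.372, and 17 were at least as high as the real value. The covariance exceeded its simulated value by 0.0208 with all arrays and by 0.0783 without the 2 arrays that stand apart.

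The workbook's columns for mock replicates 2 and 3 hold each other's scanner values. The exchange changes no group and so no comparison without a replicate block. Under the workbook's numbers, the mock array that stands apart carries number 3, as does the (+)-borneol array that stands apart.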
